A study of Mus musculus with 106 samples.

How the data were processed

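The series covers mouse liver of WT and Foxa2 mutant animals 4 h after vehicle, the FXR agonist GW4064 or the LXR agonists GW3965 and T09, in 106 samples and 45 groups. The 27 peak lists were used: 4 of ATAC-seq (ligand over vehicle), 5 of Foxa2, 4 of FXR, 6 of LXR and 8 of PPAR ChIP-seq. The 37 RNA-seq samples were not used here, nor were 8 ATAC samples of the mutant with LXR agonists and vehicles. Labels of the LXR samples give the agonist as GW without a number, and lists of these were set beside GW3965 lists. Titles ending in -Veh were read as the vehicle arm of the experiment with that ligand. The series text speaks of injection and the sample labels, where they give a route, of oral gavage for every ligand. The series text also gives 3 replicates for Foxa2 and 4 for LXR, where the samples used here number 1 per Foxa2 group and 1 (WT) or 3 (mutant) per LXR group.

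Reads were aligned with BWA to mm10 and, for RNA, handled with STAR, RSEM and edgeR per the submitters' processing notes, with versions not given. Peaks were called against input, or for ATAC ligand against vehicle, by PeakSeq per the labels. In 19 lists the authors deposited a q-value (FDR) for each peak, and all 19 were in order of q. The fold, or enrichment ratio over control, of each peak is the authors' own, as deposited, and no fold was recomputed. The -log10 of p in the 2 mutant FXR lists and the 3 ATAC lists other than WT GW4064 was the authors' own, as deposited, and was not used here. The 8 lists without q (the 5 Foxa2 lists, the 2 WT FXR lists and the WT GW4064 ATAC list) were taken in the order of their entries for every choice by rank, including the peaks given at members of gene lists. Width was used where the text says so. Positions were read as deposited and are given 1-based. The largest q was 0.015 in the mutant FXR lists, which also held 28147 (vehicle) and 7254 (GW4064) blank entries that were left out, 0.05 in the LXR and ATAC lists and about 0.07 in the PPAR lists. The names of the LXR lists give a looser FDR for the mutant than for WT, although no q in either was above 0.05.

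Many ChIP peaks were narrow. The median width was 58 bp for FXR with GW4064 in WT, 40 bp in the mutant, 39 bp for LXR with GW in WT and 276 bp for Foxa2 with GW3965, and 24.1% of the FXR peaks of WT with GW4064 were 20 bp or less. Regions found in lists of all 4 antibodies numbered 102 (389.5 kb in total, at 1600014C10Rik, Sfi1 and the Ugt1a cluster among others), and 3 of them were in every one of the 23 ChIP lists. They are called shared regions in the text.

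Lists were compared by the percent of peaks of the first list that overlapped the second by at least 1 base, with a 95% interval from 1000 bootstraps of chromosomes and a one-sided p from 100 random placements of the second list on the same chromosome beyond its first 3 Mb. Gene lists were tested by the number of members with a peak centre in the gene or within 10 kb, against 10000 random sets from 21887 protein-coding genes matched in 20 bins of gene length, a permutation over genes whose smallest possible unadjusted p is 0.0001, with Benjamini-Hochberg adjustment over the 15 lists. Random genes were drawn singly, so these p do not allow for neighbouring members that share a peak. Abcg5 and Abcg8 did so in the FXR list of WT with GW4064. The percent of each gene body inside gained ATAC regions, its 25% limit and the tests on it, including the exact binomial test on genes covered in only 1 comparison of a pair, were chosen after seeing the data, as were the first 500 peaks without shared regions, the removal of shared regions and the limits of 5 kb and 50 kb from either gene end. Named genes were, for each receptor, up to 20 members of its target list ordered by the number of lists with a peak and then by rank, plus the nearest gene of the first 5 peaks of each ligand list. For Foxa2 and ATAC they were members of the identity and receptor lists in the same order. Genes of other lists with high coverage (Hp, Socs3, Saa1, Saa2, Cxcl1, Sds, Got1, Fbp1, Dbp, Gstm1, Gstm3, Cyp2c29, Ugt1a1, Gdf15, Insig2) and the first entries outside shared regions were chosen after their values were seen. With 10% and 30% of simulated peaks placed on Foxa2 peaks, the overlap step found 10.2% and 30.15%, and 0.220% with none placed.

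Motifs were not run because no genome sequence was at hand, and distances to start sites were not run because the gene table gave no strand. The analysis used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.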

Results

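The Foxa2 gene, which encodes the forkhead factor missing from the mutant livers, carried Foxa2 peaks in its own surroundings in WT liver. Each of the 5 Foxa2 lists held 3 or 4 peaks within 10 kb of Foxa2, and with GW4064 the best placed of them lay at 2:148040145-148040568 (mm10), 2520 bp from the gene. No FXR, LXR or PPAR list of either genotype held a peak there, and the gene body lay in no region of gained accessibility in either genotype with GW4064. Within 10 kb of the gene, 3 regions were gained with GW3965 and 4 with T09 in WT, covering 0% of its body. With GW4064 the number within 10 kb was 0 in either genotype. These lists do not measure the deletion itself, and Foxa2 transcripts were not analysed here. Each group or comparison was given as 1 list, with 1 sample labelled for each Foxa2 and each WT LXR group, 3 for each mutant LXR group, 2 for each FXR and PPAR group and 2 or 3 per arm for ATAC, so each p below is over genomic placement or over gene sets and not over animals.

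Foxa2 in WT liver lay near genes of bile acid handling, plasma proteins and intermediary metabolism. With vehicle, 21 of 27 bile acid genes had a Foxa2 peak in the gene or within 10 kb of it (3.50 for random genes of matched length, adjusted permutation p = 0.0003), as did 17 of 24 hepatocyte identity genes (random 2.55, adjusted p = 0.0003). Peaks near Fga and Fgb (fibrinogen chains), Abcc2 (a canalicular export pump), Apoe, Ahsg, Klb (the co-receptor for FGF15 and FGF21), Cyp8b1 (sterol 12-alpha-hydroxylase), Hnf4a, Nr0b2 (the corepressor SHP) and Nr1h4, which encodes FXR itself, were present in all 5 Foxa2 lists. The Abcc2 peak at 19:43811441-43811751 was entry 14 of the GW4064 list, and the Fga peak at 3:83020434-83020789 was entry 8. With GW3965 the counts were 25 of 27 bile acid, 32 of 34 fatty acid oxidation, 14 of 14 gluconeogenesis, 18 of 18 clock and 15 of 17 acute phase genes (random 10.8, 12.8, 5.52, 7.83 and 4.81, adjusted permutation p = 0.0002 for each).

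Among markers of other liver cells, no Kupffer cell marker of 12 had a Foxa2 peak with GW3965 (random 4.44, adjusted permutation p = 0.0435) or with T09 (random 4.57, adjusted p = 0.0375), and no stellate cell marker of 12 had one with either vehicle (random 1.68 and 2.27, neither called below random). Sinusoidal endothelial markers had a Foxa2 peak in 6 of 12 cases in the list from vehicle of the LXR agonist experiment (random 1.81, adjusted permutation p = 0.007) and in 6 of 12 in the list from vehicle of the GW4064 experiment (random 2.62, adjusted p = 0.0422). Among the first 500 peaks of the Foxa2 lists most of these calls were lost, but hepatocyte identity genes stayed above random in every list, with 5 of 24 for vehicle (random 0.330, adjusted permutation p = 0.003).

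**Figure D1:**
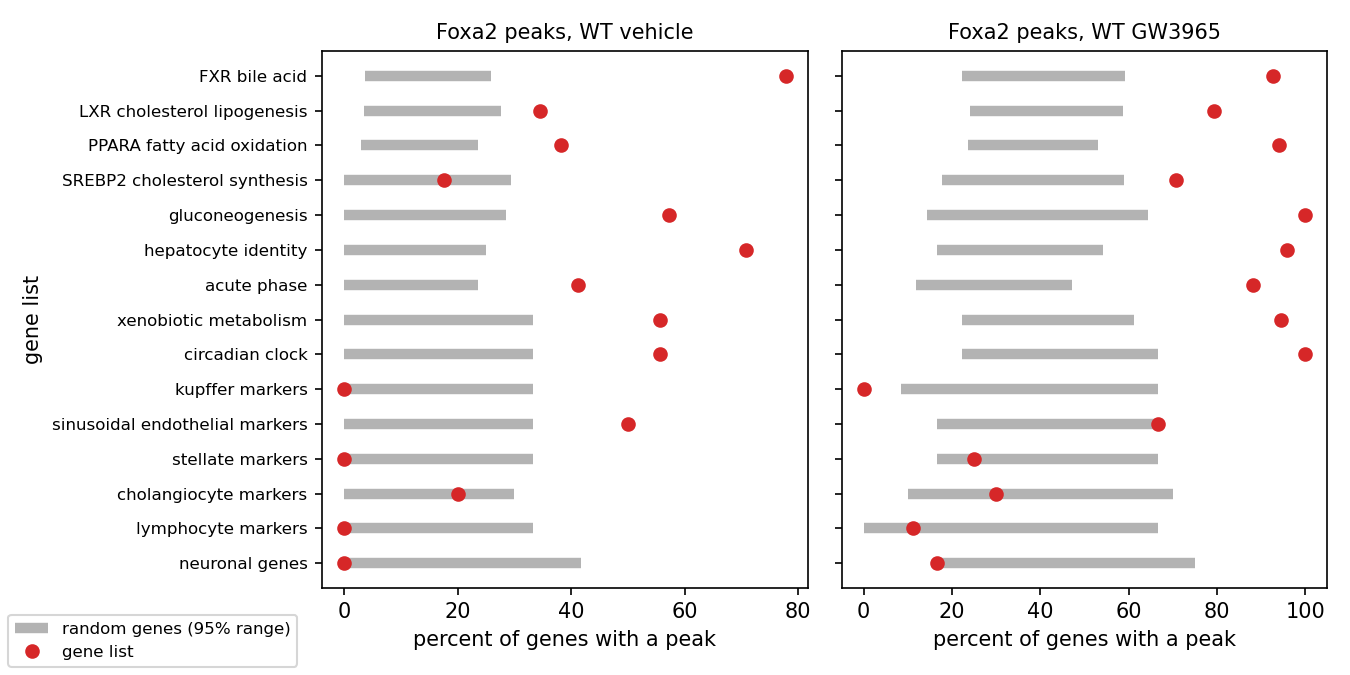
Percent of the genes of each list with a Foxa2 peak in the gene or within 10 kb, for WT vehicle and WT GW3965, beside the 95% range of random genes of matched length.

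Foxa2 lists with ligand were longer than the lists with vehicle, and their first entries were largely held in common. Lifr (the leukemia inhibitory factor receptor), Setd4 and Fga stood among the first peaks with and without ligand. The GW3965 list held 21245 peaks, the T09 list 25318 and the vehicle list 4348, and 98.8% of vehicle peaks were found again with GW3965 (95% bootstrap interval 98.4 to 99.1) and 97.2% with T09 (96.8 to 97.6). In the GW4064 experiment 64.6% of vehicle peaks were found again with ligand (63.0 to 66.3). Read the other way, 20.1% of GW3965 peaks, 16.6% of T09 peaks and 20.8% of GW4064 peaks overlapped a vehicle peak, against 0.110%, 0.114% and 0.1% after shuffling (permutation p = 0.0099 for each, the smallest possible). Those percents rose to 98.8, 99.8 and 99.8 for the first 500 peaks and to 73.6, 73.3 and 56.3 with both lists at the length of the shorter, so the low shares lie in the later entries of the longer lists.

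GW3965 and T09, both LXR agonists, gave Foxa2 lists that overlapped in part. Of the GW3965 peaks, 58.0% overlapped a T09 peak (57.1 to 59.0), and 48.8% of T09 peaks overlapped a GW3965 peak (46.9 to 51.4). Srebf1 (the lipogenic transcription factor SREBP1) and Cyp7a1 (the first enzyme of bile acid synthesis) had Foxa2 peaks with GW3965, T09 and GW4064 and with neither vehicle. The longer ligand lists lay near 36.92% (GW3965), 39.18% (T09) and 38.79% (GW4064) of all genes. The vehicle lists lay near 12.1% and, in the GW4064 experiment, 17.75%, so a peak listed with ligand and not with vehicle was common among genes. Foxa2 peaks lay inside regions of gained accessibility in 25.01% of cases with GW3965 (23.1 to 27.0, shuffled 1.62), 3.89% with T09 (3.57 to 4.20, shuffled 1.42) and 5.84% with GW4064 (5.41 to 6.25, shuffled 1.15), with permutation p = 0.0099 for each. The intervals for GW3965 and T09 lay apart, and 27.4% of Foxa2 peaks from vehicle (25.1 to 29.9) also lay in regions gained with GW3965.

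FXR in WT liver given GW4064, its agonist, occupied well known targets. Peaks lay 882 bp from Nr0b2 (4:133557396-133557739, entry 47), beside Slc51b, which encodes a subunit of the basolateral bile acid exporter (9:65422834-65423060, entry 104), in Scarb1, the HDL receptor (5:125313406-125313623, entry 125), in Osgin1 (8:119430250-119430549, entry 135) and 71 bp from Abcb11, the bile salt export pump (2:69342574-69342799, entry 140). Outside regions shared by all 4 antibodies, the first entries lay near Ptgds, Slc9a8, Zc3h6, Usp2, Zfp292, Klf9 and Cth. A peak lay within 10 kb of 16 of 27 bile acid genes (random 8.27, adjusted permutation p = 0.0225) and of 7 of 10 cholangiocyte markers (random 2.94, adjusted p = 0.045), the latter all from entries beyond the first 500. Both calls ended with the limit at 5 kb (13 of 27 and 6 of 10, adjusted permutation p = 0.072 for each) and at 50 kb (21 of 27 and 9 of 10, adjusted p = 0.211 for each), whereas among the first 500 peaks 5 of 27 bile acid genes were called (random 0.484, adjusted p = 0.0015).

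Without ligand FXR was already present at several of these genes. Nr0b2, Slc51b, Scarb1 and Osgin1 had FXR peaks with vehicle too, at overlapping positions such as 8:119430265-119430568 in Osgin1, whereas the Abcb11 peak and a peak in Cyp27a1 (sterol 27-hydroxylase) were listed with GW4064 and not with vehicle. The ligand list held 22705 peaks and the vehicle list 7883, and 1.98% of ligand peaks overlapped a vehicle peak (1.72 to 2.28, shuffled 0.0625, permutation p = 0.0099). Among the first 500 ligand peaks the share was 45% (39.3 to 50.4).

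In Foxa2 mutant liver none of these FXR target sites was listed. Nr0b2, Slc51b, Scarb1, Osgin1, Abcb11 and Cyp27a1 had no FXR peak within 10 kb in either mutant list, and 2 of 27 bile acid genes had one with GW4064 (random 1.68), namely Abcb4 and Abcg5, at entries 1030 and 2187. The first mutant entries with GW4064, outside regions shared by all antibodies, lay near Smok2b, Tcp10c and Vmn2r115. The mutant lists held 3901 peaks with GW4064 and 4284 with vehicle, and 125 WT ligand peaks, or 0.551%, overlapped a mutant ligand peak (0.338 to 0.826, shuffled 0.0389, permutation p = 0.0099). That share was 2.4% for the first 500 WT peaks and 0.248% without regions shared by all antibodies. Mutant ligand and mutant vehicle lists shared 1.90% (1.15 to 2.81, shuffled 0.0451), and 0.737% without the shared regions.

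FXR peaks met Foxa2 peaks at the highest rate at the head of the WT list. In Osgin1, Foxa2 peaks at 8:119430251-119430520 and 8:119434663-119434847 lay on FXR peaks of the same GW4064 experiment, and a Foxa2 peak at 2:69342976-69343156 lay next to the Abcb11 FXR peak. Over the whole WT list with GW4064, 1.68% of FXR peaks had a Foxa2 peak (1.49 to 1.87, shuffled 0.216), and among the first 500 it was 22% (110 peaks). In the mutant 1.97% of FXR peaks with GW4064 lay at the place of a WT Foxa2 peak (1.16 to 3.11, shuffled 0.252), falling to 0.658% without the shared regions, and 1.4% of the first 500. Peaks kept in the mutant had a Foxa2 peak in 35.2% of cases (44 of 125) and peaks lost in 1.49%, a difference of 33.7 percentage points (24.2 to 46.1) that fell to 5.74 (0.298 to 13.4) without the shared regions and turned to -5.46 (-22.2 to 23.8) for the first 500.

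**Figure D2:**
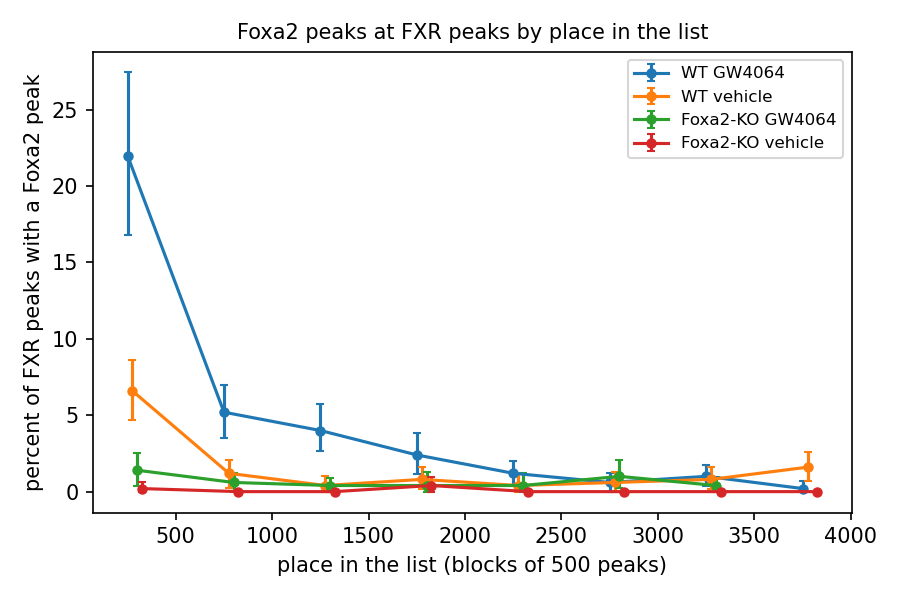
Percent of FXR peaks with a Foxa2 peak of the same treatment, in blocks of 500 peaks by place in each FXR list, with 95% bootstrap intervals and without regions shared by all antibodies.

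**Figure D3:**
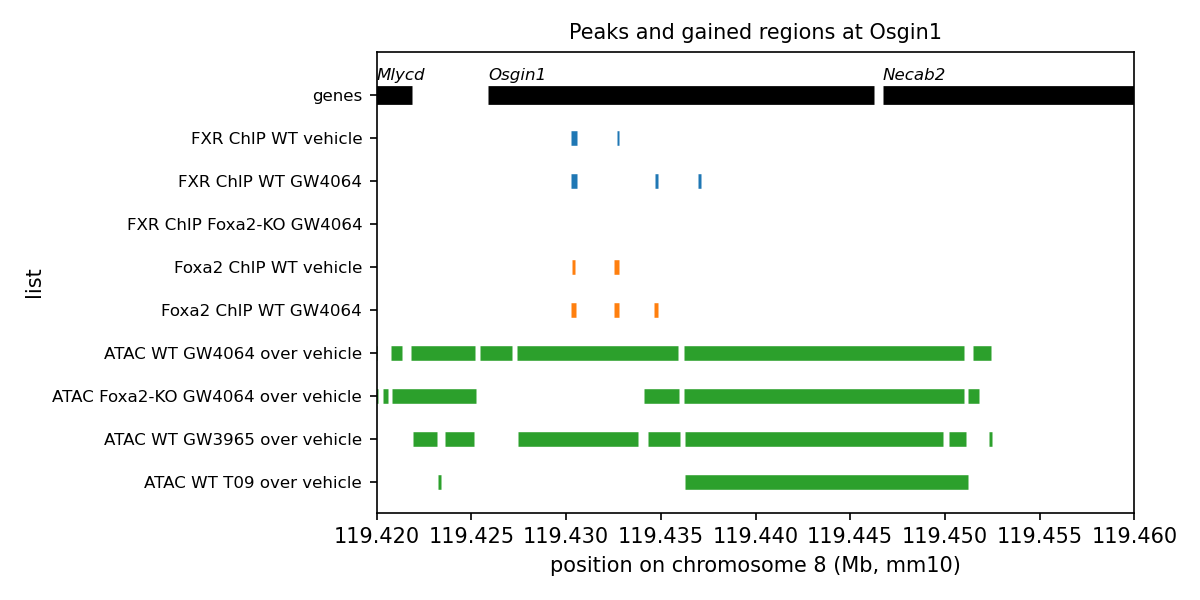
FXR peaks, Foxa2 peaks and regions of gained accessibility around Osgin1 on chromosome 8 (mm10).

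LXR in WT liver lay in Srebf1, its classical lipogenic target, with each treatment. The peak stood at 11:60210508-60210702 with the agonist labelled GW (entry 64), at 11:60210507-60210708 with T09 (entry 94) and at 11:60210496-60210743 with vehicle (entry 87), while the mutant GW list held a peak elsewhere in the gene, at 11:60203366-60203501 (entry 1264). The T09 list also held peaks near Elovl5 (a fatty acid elongase, entry 60, with an overlapping peak in the vehicle list) and Scd1 (stearoyl-CoA desaturase, 19:44388567-44388800, entry 85, with an overlapping peak in the GW list) and in Acaca (acetyl-CoA carboxylase, entry 153) and Elovl6 (entry 498). LXR target genes had a T09 peak within 10 kb in 12 of 29 cases (random 4.52, adjusted permutation p = 0.012), a GW peak in 9 of 29 (random 7.99) and a vehicle peak in 6 of 29 (random 2.88). The T09 call ended at 5 kb (9 of 29, adjusted permutation p = 0.115) and at 50 kb (12 of 29, adjusted p = 0.356) and held among the first 500 peaks (5 of 29, random 0.425, adjusted p = 0.003).

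In the Foxa2 mutant the LXR lists were shorter and held no excess of peaks near these targets. They held 8803 peaks with GW, 2503 with T09 and 161 with vehicle, against 14219, 8095 and 4803 in WT, and reached 16.27%, 7.849% and 0.4889% of all genes against 25.46%, 14.62% and 9.38%. The counts were 3 of 29 with GW (Srebf1, Smpdl3a and Abcg8), 2 of 29 with T09 (Acacb and Nr1h2) and 0 of 29 with vehicle, none above random (4.96, 2.52 and 0.167), and the difference from WT was not tested. Leading mutant entries lay at the ends of Cenpu, Ints10 and Wwox and in Eps15 and Arid1a. WT peaks overlapped a mutant peak in 2.23% of cases with GW (1.79 to 2.75), 2.15% with T09 (1.61 to 2.80) and 2.498% with vehicle (1.67 to 3.36), against 0.0629%, 0.0271% and 0.00854% after shuffling (permutation p = 0.0099 for each). For the first 500 WT peaks the shares were 11.8%, 10.8% and 11.4%. WT ligand and vehicle lists shared 1.84% with GW (1.41 to 2.33) and 2.75% with T09 (2.16 to 3.44), or 14% and 12.2% of the first 500.

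LXR peaks rarely met Foxa2 peaks. In WT the shares were 0.759% with GW against the Foxa2 list of GW3965, 2.22% with T09 and 0.937% with vehicle (shuffled 0.352, 0.442 and 0.0668, permutation p = 0.0099 for each), and without the shared regions 0.404% (permutation p = 0.0792), 1.21% and 0.320%. In the mutant they were 1.17%, 4.36% and 16.1%, the last from a list of 161 peaks of which 33.5% lay in shared regions, and 0.723%, 1.69% and 4.67% without these. WT LXR peaks kept in the mutant had a Foxa2 peak more often than those lost, by 15.4 percentage points with GW (8.98 to 22.7) and 37.7 with T09 (22.7 to 52.7), or 3.92 (1.48 to 6.61) and 9.19 (3.54 to 15.7) without the shared regions.

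PPAR lists named few genes of fatty acid oxidation. Acadl (long-chain acyl-CoA dehydrogenase, 1:66837124-66837270, entry 166) and Acaa2 (a mitochondrial thiolase) had a peak in the WT vehicle list, and Creb3l3 and Cyp4a10 in the mutant vehicle list, so the counts were 2 of 34 in each (random 1.08 and 1.86) and 0 of 34 in the 6 lists with ligand. WT peaks overlapped mutant peaks in 14.4% of cases with vehicle (10.6 to 18.7), 82.7% with GW3965 (73.6 to 89.6, from 110 peaks), 23.6% with T09 (13.2 to 60.3, from 373 peaks) and 11.1% with GW4064 (7.71 to 15.3), all with permutation p = 0.0099. Without the shared regions these became 9.99%, 77.9%, 15.6% and 6.64%. PPAR peaks with a Foxa2 peak made up 2.02%, 27.3%, 13.9% and 4.19% in WT and 1.17%, 3.07%, 9.43% and 5.29% in the mutant in the same order, and 0.537%, 14.3%, 5.39%, 1.34%, 0.305%, 0.846%, 3.87% and 2.49% without the shared regions.

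Accessibility gained with GW3965 spread over the bodies of lipogenic LXR targets. In the authors' deposited list the first region lay in Scd1 (19:44392363-44397732, fold 5.38 over vehicle), with Srebf1 (11:60193182-60212131, fold 1.98) and a region near Acsl1, an acyl-CoA synthetase (8:46535906-46547698, fold 2.20), close behind. Gained regions covered 94.8% of Scd1, 88.5% of Fasn (fatty acid synthase), 76.9% of Srebf1, 76.9% of Apoe, 68.6% of Cyp7a1 and all 100% of Thrsp. At least 25% of the gene was covered for 8 of 29 LXR targets (random 0.459, adjusted permutation p = 0.0007), 9 of 24 hepatocyte identity genes such as Alb (86.5%) and Apob (91.7%) (random 0.704, adjusted p = 0.0007), 5 of 27 bile acid genes (random 0.546, adjusted p = 0.0015), 4 of 34 fatty acid oxidation genes (random 0.777, adjusted p = 0.0204) and 3 of 18 clock genes (random 0.306, adjusted p = 0.0105). This limit on coverage was chosen after the data were seen. The clock call ended with the limit at 50% (1 of 18, adjusted permutation p = 0.253). By a region in the gene or within 10 kb, LXR targets, bile acid genes and fatty acid oxidation genes were called above random. Identity and clock genes were not called in that way. By the first 500 regions alone, identity genes were called (3 of 24, random 0.351, adjusted permutation p = 0.0187). Clock genes were again not called (2 of 18, adjusted permutation p = 0.114).

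T09, the other LXR agonist, gave a different set of covered genes. Among the first regions of the authors' deposited list were those in Lpin1, the phosphatidate phosphatase (12:16530820-16566840, fold 2.64), in Upp2 and in Egfr (11:16894556-16907055, fold 3.03). No LXR target of 29 reached 25% coverage, and Scd1, Fasn, Srebf1, Apoe and Thrsp stood at 0%. Genes of gluconeogenesis did in 3 of 14 cases, Sds (100%), Got1 (88.3%) and Fbp1 (65.0%) (random 0.223, adjusted permutation p = 0.004), as did 5 of 34 fatty acid oxidation genes including Acsl1 (51.6%) (random 0.549, adjusted p = 0.003) and 4 of 27 bile acid genes (random 0.372, adjusted p = 0.004). The fatty acid and bile acid calls ended with the limit at 50% (2 of 34, adjusted permutation p = 0.111, and 1 of 27, adjusted p = 0.379). By any region in the gene or within 10 kb, no list was called above random with T09. The first 500 regions alone gave calls for gluconeogenesis (4 of 14, random 0.199, adjusted permutation p = 0.003) and identity genes (3 of 24, random 0.312, adjusted p = 0.0352).

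GW3965 and T09 differed in these counts when set against random genes. GW3965 covered 8 more LXR targets than T09 (random sets centred on 0.0946, adjusted permutation p = 0.0008) and 7 more hepatocyte identity genes (adjusted p = 0.0008), and T09 covered 2 more genes of gluconeogenesis (adjusted p = 0.042). The identity and gluconeogenesis differences ended with the limit at 10% (4 genes, adjusted permutation p = 0.165, and 1 gene, adjusted p = 0.563). Against all other genes covered in only 1 of the 2 comparisons, which allows for unequal numbers of covered genes, no list was called after adjustment. The exact p at 25% was 0.0267 for LXR targets (adjusted 0.4), 0.167 for identity genes and 0.158 for gluconeogenesis (adjusted 0.836 for each). All 8 LXR targets in this test already lay on the GW3965 side. They were too few to give a call in that direction after adjustment, so its absence decides nothing. No difference was called for fatty acid oxidation genes (4 and 5 of 34, adjusted permutation p = 0.633). For bile acid genes none was called at 25% (5 with GW3965 and 4 with T09 of 27, adjusted permutation p = 0.79), but GW3965 covered more at 10% (10 and 5, adjusted p = 0.033) and at 50% (4 and 1, adjusted p = 0.003), and it covered more cholesterol synthesis genes at 10% alone (8 and 1 of 17, adjusted p = 0.0008). Dbp, a clock output gene, was fully covered with both, and 77 genes passed 25% with both compounds against 7.62 by chance, out of 495 with GW3965 and 337 with T09. Of the GW3965 regions, 4.41% overlapped a T09 region (4.07 to 4.72, shuffled 1.33, permutation p = 0.0099).

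**Figure D4:**
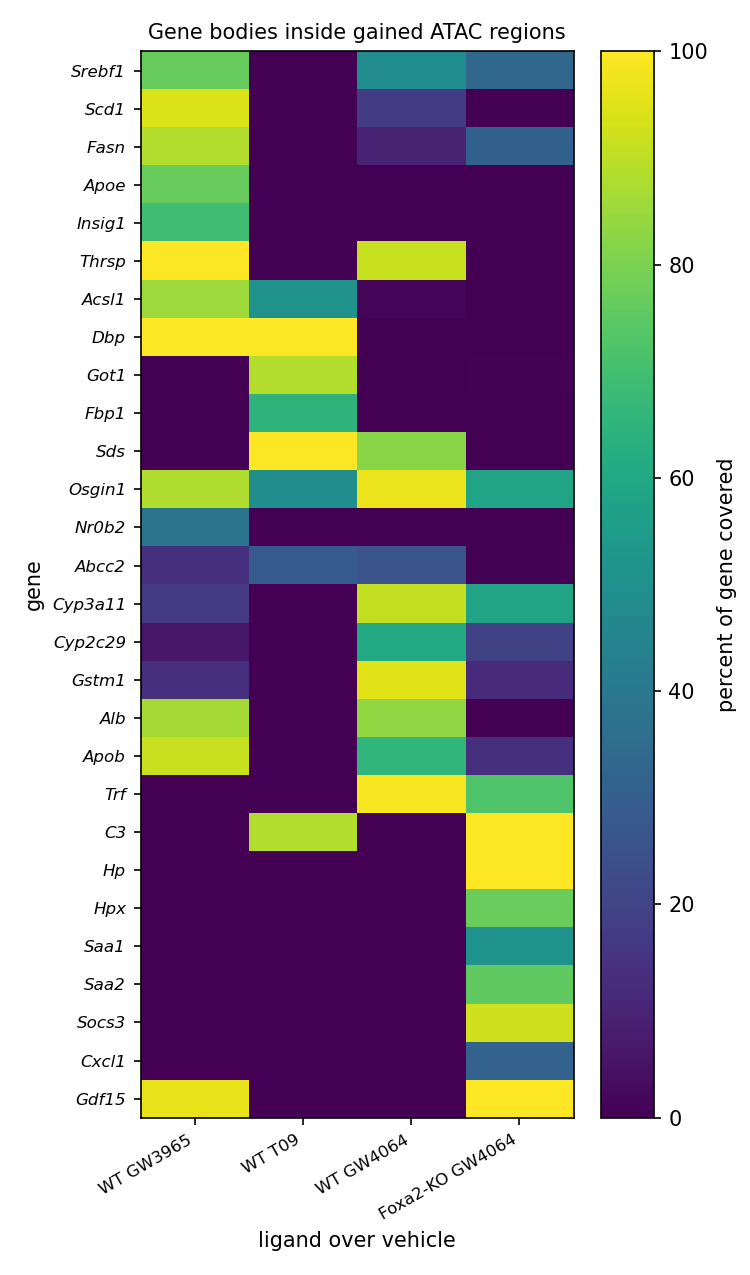
Percent of each gene body inside regions of gained accessibility, for 4 comparisons of ligand with vehicle. Most of the genes are named in the text, and they were chosen after their values were seen.

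Accessibility gained with GW4064 in WT liver covered genes of drug and xenobiotic metabolism and the bile acid target Osgin1. The first entries lay at Cyp3a11, a cytochrome P450 of drug oxidation (5:145851476-145857144), Cyp3a25 (5:145982353-145990608), Osgin1 (8:119436245-119451028) and Gstm3, and gained regions covered 96.9% of Osgin1, 95.3% of Gstm1, 90.9% of Cyp3a11 and 60.8% of Cyp2c29. By width the longest lay in Apob and Trf. Xenobiotic genes passed 25% in 4 of 18 cases (random 0.286, adjusted permutation p = 0.0015), hepatocyte identity genes in 4 of 24 (random 0.596, adjusted p = 0.0172), fatty acid oxidation genes in 4 of 34 (random 0.672, adjusted p = 0.019) and bile acid genes in 3 of 27 (random 0.487, adjusted p = 0.0349). Ugt1a1, one of the 4 xenobiotic genes, lies in a region shared by all antibodies. By a region in the gene or within 10 kb, bile acid genes and LXR targets were called above random. Xenobiotic, identity and fatty acid oxidation genes were not called in that way. By the first 500 regions alone, xenobiotic genes (9 of 18, random 0.398, adjusted permutation p = 0.0015) and identity genes (4 of 24, random 0.397, adjusted p = 0.0022) were called. Fatty acid oxidation genes were again not called (3 of 34, adjusted permutation p = 0.0801). The fatty acid call ended with the limit at 10% (4 of 34, adjusted permutation p = 0.416) and at 50% (0 of 34), and the bile acid call at 50% (1 of 27, adjusted p = 0.436).

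In Foxa2 mutant liver accessibility gained with the same ligand lay at genes of the acute phase response. Regions gained over vehicle covered 100% of Hp (haptoglobin), 92.9% of Socs3 (a feedback inhibitor of cytokine signalling), 75.6% of Saa2 and 50.8% of Saa1 (serum amyloid A) and 31.3% of Cxcl1, each at 0% in WT, and Hpx (hemopexin), Fgf21 and Gdf15 stood at 77.2%, 75.0% and 100%, again at 0% in WT with GW4064, although Gdf15 was covered to 96.85% in WT with GW3965. In the authors' deposited list the region in Hpx (7:105589134-105598177, fold 1.78) and that beside Saa2 (7:46752525-46756276, fold 2.66) were entries 4 and 5, behind regions beside Cyp3a25 (fold 3.26) and Insig2 (fold 2.74). Acute phase genes passed 25% in 5 of 17 cases (random 0.655, adjusted permutation p = 0.006) against 0 of 17 in WT. By any region in the gene or within 10 kb, acute phase genes were not called (14 of 17, random 10, adjusted permutation p = 0.492). Nor was any list called above random in the mutant in that way. By the first 500 regions alone, acute phase genes were called in the mutant (7 of 17, random 0.292, adjusted permutation p = 0.0015). In WT 0 of 17 lay near the first 500 regions (random 0.223). LXR targets passed 25% in the mutant in 3 of 29 cases (random 0.306, adjusted permutation p = 0.0232), a call that ended at 50% (0 of 29).

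Some gained regions of the WT were seen in the mutant as well. Osgin1, Cyp3a11 and Trf were covered to 58.4%, 58.3% and 72.6% in the mutant, whereas Alb, covered to 83.6% in WT, and Thrsp, to 91.5%, stood at 0%. Genes passing 25% numbered 424 in WT and 364 in the mutant, with 79 in both against 7.05 by chance. Acute phase genes differed by 5 in favour of the mutant (adjusted permutation p = 0.0015) and xenobiotic genes by 3 in favour of the WT (adjusted p = 0.0127), and both held at 10% and 50% against random genes. Against all other genes covered in only 1 genotype, neither was called after adjustment (at 25% exact p = 0.0181, adjusted 0.271, and exact p = 0.256, adjusted 1). All 5 acute phase genes and all 3 xenobiotic genes in this test already lay on 1 side. They were too few to give a call after adjustment, so its absence decides nothing. The xenobiotic genes Cyp2c29 and Gstm1, past 25% in WT alone, were also covered in the mutant, to 19.26% and 12.33%. Bile acid genes differed at the 10% limit (9 of 27 in WT and 2 in the mutant, adjusted permutation p = 0.0008) and were not called at 25% (3 and 1, adjusted p = 0.327) or 50% (1 and 1). Near a gained region, hepatocyte identity genes were fewer in the mutant than for random genes (9 of 24, random 15.8, adjusted permutation p = 0.039), and Kupffer cell markers were fewer in WT (2 of 12, random 7.40, adjusted p = 0.018). Of the WT regions, 5.33% overlapped a mutant region (4.93 to 5.72, shuffled 1.85, permutation p = 0.0099), and 28.8% of the first 500 did.

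Gained regions were shared between ligands more often than after shuffling. Osgin1 passed 25% coverage with all of GW4064 (both genotypes), GW3965 and T09. GW3965 regions overlapped GW4064 regions of WT in 5.38% of cases (4.97 to 5.78, shuffled 1.55) and those of the mutant in 3.26% (3.00 to 3.51, shuffled 1.77), and T09 regions did in 4.71% (4.42 to 5.02, shuffled 1.37) and 4.35% (4.13 to 4.57, shuffled 1.53), all with permutation p = 0.0099. For the first 500 regions the GW3965 share with the mutant was 5.0% against 9.12% after shuffling, a shortfall that was not tested.

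FXR peaks lay inside regions gained with GW4064 most often at the head of the WT list. Nr0b2, Abcb11 and Slc51b, whose FXR peaks are given above, had gained regions over 0%, 21.8% and 0% of their bodies in WT. In all, 1.54% of WT FXR peaks lay in a gained region (1.33 to 1.74, shuffled 1.03) and 17% of the first 500, against 2.10% in the mutant (1.45 to 2.77, shuffled 1.16) and 2.4% of the first 500 there (permutation p = 0.0594). LXR peaks did so in 2.45% of cases with GW (2.13 to 2.81, shuffled 0.973) and 1.88% with T09 (1.37 to 2.41, shuffled 0.802). PPAR peaks did in 7.27% with GW3965, 2.41% with T09 (permutation p = 0.0396), 2.27% with GW4064 and 4.05% with GW4064 in the mutant, and the 3 WT calls ended with every peak at 400 bp. All other p in this comparison were 0.0099.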

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

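The tests in this part were chosen after the result was seen. With GW4064 over vehicle, the genotypes differed in the test of the difference for 2 gene lists: acute phase genes covered to at least 25% were 5 more in the Foxa2 mutant (adjusted permutation p = 0.0015) and xenobiotic genes 3 more in WT (adjusted permutation p = 0.0127). The xenobiotic genes Cyp2c29 and Gstm1 passed 25% in WT alone but were also covered in the mutant, to 19.26% and 12.33%. Ugt1a1, another xenobiotic gene past 25% in WT, lies in a region shared by all antibodies. At the 10% limit bile acid genes differed as well, 9 in WT and 2 in the mutant (adjusted permutation p = 0.0008), which was not called at 25% or 50%. These p are against random genes of matched length. Against all other genes covered in only 1 genotype, the xenobiotic difference was not called at any limit (exact p = 0.256, 0.0792 and 0.108 at 25%, 10% and 50%), nor the bile acid one after adjustment (exact p = 0.0466, adjusted 0.35), so unequal coverage of the 2 lists was not excluded for them. All members in these tests lay on the WT side and were too few to decide it.

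For the acute phase genes (Hp, Socs3, Saa1, Saa2, Cxcl1), a larger yield of covered genes in the mutant was considered as the cause. Such a larger yield was not seen among the other genes at 25% and 10%. Other genes covered in 1 genotype only numbered 280 in the mutant and 345 in WT at 25%, and 669 and 942 at 10%. At 50% they numbered 127 and 122. Of the genes covered to 25% in 1 of the 2 genotypes, 5 of 5 acute phase genes and 44.8% of the others were covered in the mutant (exact binomial p = 0.0181, adjusted 0.271), at 10% 6 of 6 and 41.53% (exact p = 0.00513, adjusted 0.0769), and at 50% 4 of 4 and 51% (exact p = 0.125, adjusted 0.94). All of these acute phase genes already lay on the mutant side, so they were too few for this test to decide. The mutant list held more regions (82561 and 60528 in WT) and reached more genes (68.05% and 62.15%), with fewer genes covered to 25% (364 and 424) and about as many to 50% (158 and 149). Near the first 500 regions lay 7 of 17 acute phase genes in the mutant (random 0.292, adjusted permutation p = 0.0015). In WT 0 of 17 did (random 0.223), and this difference was not tested. The excess over random genes in the mutant thus did not depend on the longer list. More immune cells in the mutant livers given GW4064 could also bring such genes. Kupffer and lymphocyte markers had a gained region nearby in 11 of 21 cases (random 13.8). The limits of the 2 marker lists added together were 8 to 19, which is wider than the range of their joint count. No excess of these markers was seen, which leaves this open. An inflammatory reaction in some animals stays open and untested, since 1 list stands for all the samples of each comparison. An effect of the Foxa2 genotype on the response to GW4064 stays among the open explanations, as untested.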

How the results depend on the processing

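The overlap rules, widths, ranks by q, autosomes and gene pool were set before the data were examined, and ranks by order of entry (for lists without q), the removal of shared regions, the first 500 peaks, the limits of 5 kb and 50 kb and the coverage limits were chosen after seeing the data. No paired analysis was possible because each group was given as 1 list. Alternatives by start site (5 kb and 50 kb) and all motif alternatives were not run. Of the overlaps under alternatives, 314 kept their direction and side of the threshold, 7 weakened and 4 reversed. Sizes moved further: by over 1.5 times for 27 of 47 overlaps with lists at the length of the shorter (0 to 21.38 times the main value), for 26 of 40 among the first 500 peaks (0.2954 to 22.76) and for 26 of 47, all down, without shared regions. At 400 bp the kept minus lost difference fell from 33.71 to 17.56 for FXR, from 15.36 to 7.455 for LXR with GW and from 37.67 to 21.34 with T09. Without shared regions, FXR of mutant vehicle met Foxa2 in 0.0709% of cases (shuffled 0.0742), LXR of WT with GW in 0.404%, and PPAR of WT with T09 lay in gained regions in 1.497%. For the first 500 peaks, FXR of mutant vehicle met Foxa2 in 0.2%, FXR of the mutant with GW4064 lay in gained regions in 2.4%, GW3965 regions met mutant GW4064 regions in 5.0%, and the kept minus lost difference for FXR was -5.46. With every peak at 400 bp, PPAR of WT lay in gained regions in 4.55% (GW3965), 2.15% (T09) and 2.32% (GW4064) of cases, and with lists at the length of the shorter in 0% (GW3965) and 0% (T09), where 110 and 373 regions were left. For bile acid genes near FXR of WT with GW4064 the counts were 13 at 5 kb and 21 at 50 kb, and for LXR targets near LXR of WT with T09 they were 9 and 12, none of them past the threshold any longer. Bile acid genes near FXR of WT vehicle were called among the first 500 peaks (4 of 27, adjusted permutation p = 0.015). The first 500 peaks had 0 cholangiocyte markers for FXR of WT with GW4064, and for Foxa2 0 gluconeogenesis genes (GW3965, GW4064, both vehicles), 0 clock genes (GW3965, T09, vehicle), 0 cholesterol synthesis genes (GW3965, T09), 0 fatty acid oxidation genes (GW4064, vehicle), 0 xenobiotic genes (vehicle of GW4064) and 0 endothelial markers (vehicle), each with under 1 by chance. Fewer peaks leave fewer genes reached in that setting, and for the other changes the cause was not tested. Among gene lists near peaks 272 results stayed, 50 weakened, 14 reversed and 1 became stronger, and among coverage results 29 stayed and 9 weakened. Read depth was not given for any list, and thresholds differed between antibodies.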

Other observations

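Further genes, most of them members of the lists tested above, also lay in gained regions. Nfkbia, which encodes an inhibitor of NF-kappaB, was covered to 80.6% with GW3965 and 0% with the other comparisons, Foxa1 to 70.9% and Cebpa to 100% with GW3965 alone. Onecut1, a hepatocyte transcription factor, was covered to 74.2% and Por, the P450 reductase, to 53.7% with T09. The apolipoprotein genes Apoa1 and Apoc3 were covered to 100% with GW3965 and with T09 and to 0% with GW4064 in either genotype. C3, the central complement component, was covered to 100% in the mutant with GW4064 and to 88.5% in WT with T09.

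All tests in this part were chosen after the results were seen. The FXR lists of the Foxa2 mutant lacked the WT sites at Nr0b2, Slc51b, Scarb1, Osgin1 and Abcb11. Unequal thresholds as the whole cause are argued against by the first 500 peaks of each list, of which 20.6 percentage points more met a Foxa2 peak in WT than in the mutant (15.1 to 25.9). That reading takes the order of entries in the WT lists, which carry no q, as a rank. It does not show whether the missing sites lay under the mutant cutoff in libraries of weaker enrichment. A local need for Foxa2 at each FXR site as the whole cause is argued against as well, since of the 304 first WT peaks with no Foxa2 peak in any list 3.29% were kept (0.967 to 6.50), beside 1.02% of the 196 with one. A local need beside another cause stays open, because weak enrichment would remove both kinds of peaks. Weak enrichment in the mutant libraries may account for the loss, since mutant ligand peaks of the first 500 met the mutant vehicle list in 3.2% of cases (1.26 to 5.79) and WT ones the WT vehicle list in 45%. A general loss of FXR binding without Foxa2 would give the same values and stays open, untested.

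LXR targets were covered with GW3965 in 8 of 29 cases and with T09 in none. The difference lay outside the range of random genes at every limit (8, 9 and 6 at 25%, 10% and 50%), and gluconeogenesis genes went the other way, but random genes are seldom covered in either list and do not show what a lower sensitivity of the T09 comparison does to genes that are often covered. Of the genes covered to 25% in 1 of the 2 comparisons, 8 of 8 LXR targets and 61.19% of the others were covered with GW3965 (exact binomial p = 0.0267, adjusted over the 15 lists 0.4), while the exact p was 0.0605 at 10% and 0.0879 at 50%, so a lower sensitivity could be the cause and the counts are too few to decide. Feeding state or time of day of the animals could also differ between ligand and vehicle, and clock genes covered (3 and 1 of 18, adjusted permutation p = 0.0984) do not decide this, so it cannot be told apart from a compound effect. A difference between the compounds in their action on these genes stays open and was not tested.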
